A study of Mus musculus with 32 samples.

How the data were processed

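RNA was sequenced from 32 samples of mice that carry the TDP-43_Q331K transgene, a mutant form of the RNA-binding protein TDP-43 that is used to model amyotrophic lateral sclerosis. Astrocytes selected with the ACSA2 antibody came from cortices and spinal cords at 3, 6 and 10 months of age, with 4, 5 and 2 libraries. Oligodendrocyte lineage cells selected with the O4 antibody came from the same tissues at 3 and 6 months, with 4 libraries at each age. Microglia selected with Cd11b came from cortices only, at 3 months with 3 libraries and at 10 months with 4. Primary astrocytes were grown for 14 days, replated and then given vehicle or 40 µM Omomyc for 48 hours, with 3 libraries for each treatment. Omomyc is a miniprotein derived from MYC that acts as a dominant-negative MYC inhibitor. Mice without the transgene were not analysed here, so an effect of age in these samples cannot be separated from ageing without the transgene.

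Per the labels, astrocyte and oligodendrocyte libraries were made with a poly(A) kit that carries unique molecular identifiers, microglia libraries with a 3′ end kit, and culture libraries with a further mRNA kit and adapters that carry identifiers. The deposited tables used here hold raw counts per gene, 1 column per library, made by the authors without normalization. Their notes name fastp, STAR 2.7.7a, UMI-tools 1.0.1, featureCounts 2.0.1 and DESeq2 and the builds GRCm39, GRCm38.p6 and mm10, with no role or order, so which build belongs to which table is not given in the sources used here. The astrocyte and oligodendrocyte tables list 55291 genes by symbol, that of microglia 53700 genes by Ensembl identifier and that of the cultures 17572 genes by versioned Ensembl identifier. Genes had therefore been left out of the culture table by a rule not given in the sources used here. Deposited TPM and normalized tables of the same libraries were not used. Gene symbols and positions were taken from GENCODE vM21 on GRCm38, and a position applies to that annotation and not to a table's own build.

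Total counts per library were between 6151583 and 20763190 in astrocytes, 9752907 and 18598533 in oligodendrocytes, 4145129 and 5612071 in microglia, and 30117025 and 37470972 in culture. Levels are given as CPM, the count of a gene scaled to library size with TMM factors. These factors came from the tested genes or from all genes of a table, so a level can differ slightly between passages. The spread between libraries sets the precision of every value.

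All comparisons and settings in this paragraph were chosen before the data were examined. Each table was fitted on its own in edgeR 4.0.16 under R 4.3.3, with TMM normalization, filterByExpr at a minimum count of 10, a robust quasi-likelihood model with 1 mean per group and a quasi-likelihood F test, which is two-sided. The 3 ages of astrocytes shared 1 fit. The 17 astrocyte and oligodendrocyte libraries of 3 and 6 months were also joined in 1 fit, in which the cell types were compared over both ages and the age effect in oligodendrocytes was subtracted from that in astrocytes. Tables made with different kits were not joined. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and errors of log2 fold changes are standard errors from the fit. For 33 gene lists with 927 genes (MYC, metabolism, growth, stress, glial states, inflammation, matrix, disease genes and markers of the cell types that a sort could hold) camera in limma 3.58.1 tested each list of 5 or more measured genes against the other genes. It used log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided and adjusted over the lists of a comparison. The same test with a correlation estimated from the residuals was an alternative, and none of the lists passed it in any comparison. Lists called with the preset correlation are therefore given with both adjusted p values.

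Named genes followed a rule. Up to 10 genes each way were taken by size of change among called genes with at least 5 CPM in the higher group, no overlap between the groups' libraries and a symbol that was not a clone or predicted name. Up to 4 members with the smallest p were taken from each called list. The 11 genes Myc, Mycn, Max, Tardbp, Gfap, Vim, Serpina3n, C3, C4b, Cdkn1a and Apoe were looked at in every comparison, and another 11 cell type markers between the cell types. For the difference of age effects, up to 5 genes each way were taken. Genes close in sequence to another gene are called uncertain. The text mainly gives genes of the rule whose call was kept with each library left out in turn, and says where a named call was lost. Some genes of the rule are not reported here.

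Alternatives were RLE scaling, no filter, a filter at 1 CPM, DESeq2 1.42.0, limma-voom, a term for the replicate number, a fit of only the 2 ages compared and each library left out in turn. Alternatives added after seeing the data left out genes that took unequal shares of counts, took Omomyc gene sets from the fit with replicate pairs, and varied that fit. Where a library is left out of a pair, the lone library is assumed to vary like the other groups. Replicate numbers were tested as pairs by correlating residual expression between groups. Culture libraries with the same number correlated at 0.43 to 0.68, and each of the 3 was closest to its own number. The labels give only replicate numbers, so this pairing is inferred from the same expression data. A fit with a term for the pair is therefore given beside the fit without it. Planned set tests on Omomyc genes could not be run on the fit without pairs, because it called 3 genes and 1 or 0 of them was measured in each age comparison.

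The pipeline was tested on simulated data with the group sizes and spread of each comparison and 200 changed genes. At a change of 2-fold it recovered 82.1% in the 6 against 3 month astrocytes, 62.7% at 10 against 3 months, 73.1% at 10 against 6 months, 67.2% in oligodendrocytes, 32.8% in microglia and 76.1% in culture, with 0 calls of the wrong sign. False calls were between 2.08% and 11.3% of calls. Libraries were compared in 44 pairs for duplicates and none was found. Figures were drawn with matplotlib 3.10.9.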

Results

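The series measured gene expression in glia of mice with the TDP-43_Q331K transgene, in 32 RNA sequencing libraries from freshly sorted astrocytes, oligodendrocyte lineage cells and microglia and from cultured astrocytes. Its title names MYC-driven gliosis, and its samples ask which transcripts change with age in each cell type and which change with Omomyc in culture. After filtering, 16189 genes were tested in astrocytes, 14050 in oligodendrocytes, 12320 in microglia and 16119 in culture. Changes are given as log2 fold changes ± SE, and levels as CPM ± SD where an error is shown. Myc itself was at 6.38 CPM in 3 month astrocytes, 5.72 CPM in 3 month oligodendrocytes, 6.60 CPM in 3 month microglia and 32.3 CPM in vehicle cultures.

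**Figure D1:**
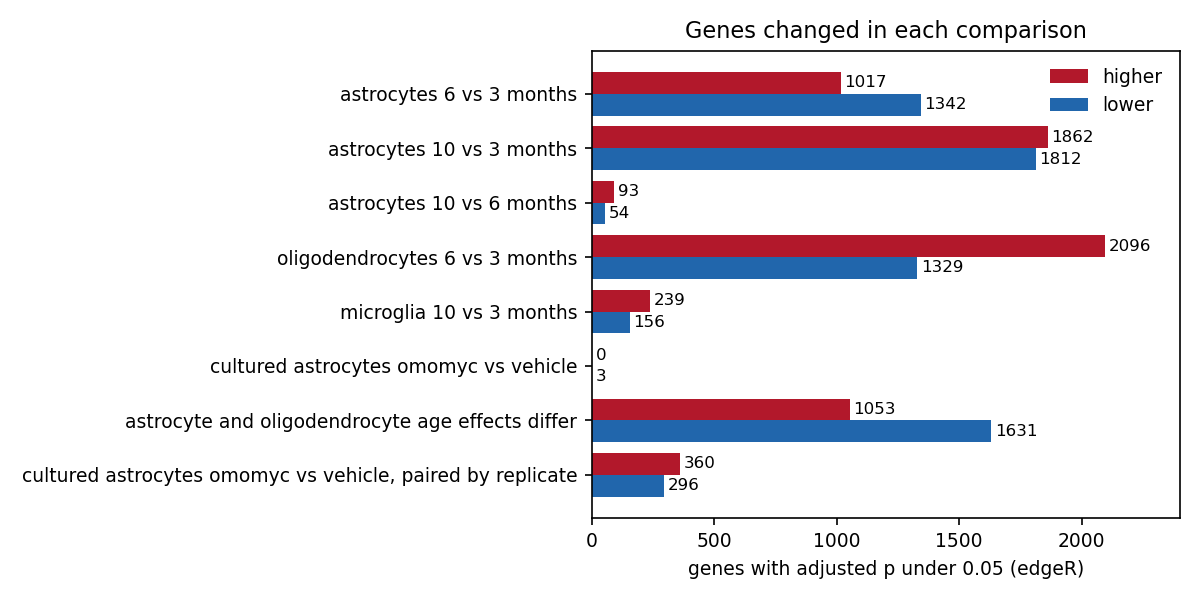
Number of genes higher (red) and lower (blue) in each comparison at an adjusted p under 0.05 in edgeR, on a linear axis from 0. Counts are between 0 and 2096 per bar, and the direct comparison of astrocytes with oligodendrocytes (6328 higher, 5874 lower) is left out.

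The comparison of 6 with 3 months asked what changed early in astrocytes (n = 5 and 4). Ciart, a transcriptional repressor of the circadian clock (chromosome 3, 95878503 to 95882251), rose by 2.09 ± 0.23, from 5.53 ± 1.39 to 24.6 ± 7.94 CPM (adjusted p = 0.000191). Dbp, a clock output transcription factor, rose by 1.63 ± 0.15, from 52.4 ± 11.7 to 161 ± 24.7 CPM (adjusted p = 8.82e-05). Hif3a (1.51 ± 0.18), a member of the hypoxia-inducible factor family, Smpdl3b (1.48 ± 0.20), the glucose transporter gene Slc2a4 (1.35 ± 0.18), Tmem59l (1.27 ± 0.16) and T2 (1.25 ± 0.22) also rose. The prolactin receptor gene Prlr fell by 2.47 on the log2 scale (SE 0.39) and Kl, which encodes klotho and is abundant in choroid plexus, by 2.35 (SE 0.48), from 23.8 to 4.67 CPM. In the same sorts the choroid plexus gene Ttr was at 721 ± 487 CPM at 3 months and 162 ± 64.8 CPM at 6 months. Usp31 (-1.36 ± 0.21), the phospholipase gene Pla2g4a (-1.31 ± 0.28), Smco3 (-1.29 ± 0.23), Tmem74 (-1.29 ± 0.27), Crybg3 (-1.24 ± 0.22) and Top2a (-1.23 ± 0.26), a topoisomerase of dividing cells, fell.

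**Figure D2:**
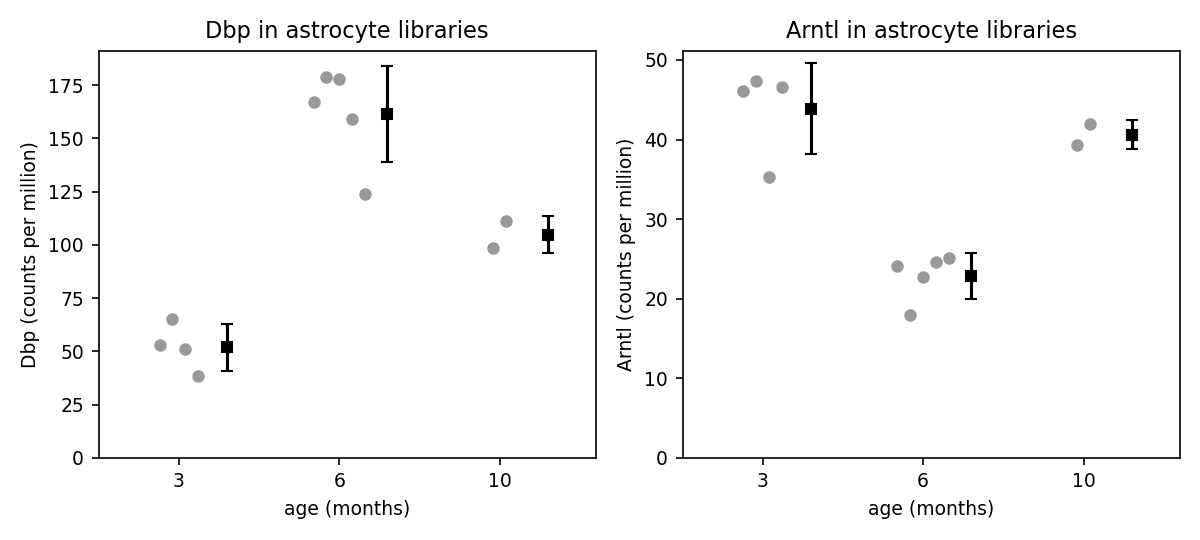
Dbp and Arntl in CPM with TMM factors in astrocytes at 3, 6 and 10 months, grey points for libraries (n = 4, 5 and 2) and black squares with bars for the mean ± SD.

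Transcripts of myelin-forming oligodendrocytes were lower in the 6 month astrocyte sorts. Of 30 myelinating oligodendrocyte genes 18 fell, 0 rose and 12 did not pass (26 lower and 0 higher adjusted over the list alone), with a list adjusted p = 6.64e-12 and adjusted p = 0.802 with an estimated correlation. Enpp2 (-0.87 ± 0.14, from 2160 to 1180 CPM), the galactolipid synthesis gene Ugt8a (-1.10 ± 0.17), Ermn (-0.92 ± 0.16) and the myelin transcription factor gene Myrf (-0.69 ± 0.13) were among them. Newly formed oligodendrocyte genes had 9 of 18 lower and 0 higher (11 lower and 1 higher adjusted over the list alone; list adjusted p = 0.000546), with adjusted p = 0.477 with an estimated correlation. They included Rap2a (-0.64 ± 0.11), Chn2 (-0.78 ± 0.14), Prom1 (-0.63 ± 0.12) and Nfasc (-0.63 ± 0.14). Of 40 cell cycle genes 3 fell and 0 rose (1 lower and 0 higher adjusted over the list alone), with a list adjusted p = 0.0167 and adjusted p = 0.802 with an estimated correlation. Endothelial genes had 2 lower and 1 higher of 21 (6 lower and 2 higher adjusted over the list alone), with Kdr, a vascular growth factor receptor gene, at -0.94 ± 0.18. Their list adjusted p = 0.0167 (adjusted p = 0.822 with an estimated correlation) rose to 0.0568 without 3 month replicate 2 and to 0.114 without 6 month replicate 5.

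Complement, antigen presentation and A1 astrocyte genes were called higher at 6 months, but not with an estimated correlation (adjusted p = 0.477, 0.478 and 0.802), and other reactive and immune lists were not called. C3, the central complement component, rose by 1.21 ± 0.25, from 8.87 to 20.3 CPM (adjusted p = 0.00618), C4b by 0.59 ± 0.14 and Ggta1, a gene of the A1 astrocyte list, by 0.74 ± 0.14. Of 15 antigen presentation genes 3 rose and 0 fell (3 higher and 0 lower adjusted over the list alone), with a list adjusted p = 0.00862. In this list the call of the peptide transporter gene Tap1 (0.86 ± 0.21) was lost without 3 month replicate 4 (0.80). Complement genes had 3 higher and 0 lower of 11 (5 higher and 0 lower adjusted over the list alone), with a list adjusted p = 0.023. The complement call was lost without 3 month replicate 1 (0.0795), 6 month replicate 1 (0.0569) or 6 month replicate 5 (0.0916). A1 astrocyte genes had 3 higher and 0 lower of 12, as when adjusted over the list alone, with a list adjusted p = 0.0198. The A1 call was lost without 3 month replicate 1 (0.0889) or 6 month replicate 1 (0.103). The microglial gene Cx3cr1 was at 2.09 ± 0.345 CPM at 3 months, 3.16 ± 0.487 CPM at 6 months and 5 ± 1.22 CPM at 10 months in these sorts. C1qc, a complement gene of microglia, was called higher (1.03 ± 0.33, from 1.13 to 2.23 CPM), but not without 3 month replicates 1 (0.84), 2 (1.05) or 4 (1.07) or 6 month replicates 1 (1.03), 3 (0.98) or 4 (0.97). Pan-reactive (1 higher and 1 lower of 10; list adjusted p = 0.643), A2 astrocyte (1 higher and 0 lower of 7; 0.624), NF-kB cytokine and chemokine (0 of 17; 0.416) and interferon response genes (4 higher and 0 lower of 32; 0.127) were not called as lists. The cell cycle inhibitor gene Cdkn1a fell (-0.92 ± 0.18). The intermediate filament gene Vim was called higher (0.43 ± 0.13), but not without 3 month replicates 1 (0.36) or 4 (0.45), or without 6 month replicates 3 (0.43), 4 (0.41) or 5 (0.35). Gfap (-0.01 ± 0.17), Myc (-0.09 ± 0.21), Mycn (-0.63 ± 0.24), Max (-0.12 ± 0.08), Tardbp (0.11 ± 0.10), Apoe (0.18 ± 0.20) and Serpina3n (-0.02 ± 0.15) did not pass the test. MYC target genes had 2 higher and 3 lower of 68 (0 and 0 adjusted over the list alone; list adjusted p = 0.709). In all, 1017 genes rose and 1342 fell in edgeR, 167 and 123 of them by at least 2-fold. This total of 2359 became 1564, 1539 and 1161 without 3 month replicates 1, 3 and 4, and 1437 and 1567 without 6 month replicates 3 and 4.

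The comparison of 10 with 3 months (n = 2 and 4) covered the longest interval in astrocytes. The collagen gene Col5a3 (chromosome 9, 20770050 to 20815067) rose by 1.81 ± 0.14, from 25.2 to 88.4 CPM (adjusted p = 3.14e-06), and the collagen gene Col7a1 by 2.09 ± 0.25. Baiap3 (2.53 ± 0.36), Ttll10 (2.14 ± 0.29), C1ql1 (2.08 ± 0.38), the potassium channel gene Kcns1 (2.07 ± 0.29), Sbsn (1.93 ± 0.41), Tnni3 (1.88 ± 0.21) and the cytokine receptor gene Crlf2 (1.88 ± 0.31) also rose. C3 rose by 1.70 ± 0.30, from 8.87 to 28.8 CPM, and C4b by 1.06 ± 0.18, from 84.6 to 177 CPM. Prlr fell by 4.81 on the log2 scale (SE 0.72), the carbonic anhydrase gene Car12 by 4.36 (SE 0.83) and Mfrp by 3.64 (SE 0.71). Kl went from 23.8 to 0.154 CPM and Tmem72 from 6.26 to 0.107 CPM, with so few counts left at 10 months that no fold is given. The choroid plexus transport protein gene Ttr was called lower (-5.68 ± 1.38), but its call was lost without 10 month replicate 2 (-4.65) and in a fit of the 2 ages alone (-5.73). Ttr was at 196 to 1330 CPM between 3 month libraries and 0.093 to 28.9 CPM between 10 month libraries. Whether Prlr, Car12, Mfrp, Kl and Tmem72 fell with Ttr through choroid plexus RNA in the sorts was not tested. CT010467.1, listed under a clone name, took 2.21% to 4.82% of counts at 3 months and 0.243% to 0.290% at 10 months. Its log2 fold change was -3.72 (SE 0.53). Whether this share changed in the cells or through library preparation was not tested.

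Immediate early genes, which respond within minutes to stimulation, had 14 higher and 0 lower of 28 at 10 over 3 months (15 higher and 0 lower adjusted over the list alone). Their list adjusted p = 0.00397, and adjusted p = 0.968 with an estimated correlation. The 10 month libraries also differed in RNA composition, with a mean share of counts at 3 and 10 months of 3.1% and 0.266% for CT010467.1, 0.933% and 0.0955% for mt-Rnr2, 0.134% and 0.017% for Lars2 and 0.269% and 0.0816% for the nuclear RNA Malat1. Ier2 (1.78 ± 0.26), Junb (1.65 ± 0.22) and Jun (0.82 ± 0.14, from 154 to 272 CPM), the latter pair parts of the AP-1 transcription factor, were among them. Myelinating oligodendrocyte genes had 16 lower and 0 higher of 30 (18 lower and 1 higher adjusted over the list alone; list adjusted p = 8.78e-07), with adjusted p = 0.968 with an estimated correlation. Tspan2 (-1.28 ± 0.19, from 979 to 403 CPM) and Enpp2 (-1.10 ± 0.19) fell. Newly formed oligodendrocyte genes had 8 lower and 2 higher of 18 (9 and 2 adjusted over the list alone), with Tmem163 at -1.01 ± 0.21 and Kif19a, a kinesin gene, higher by 0.80 ± 0.14. Their list adjusted p = 0.0426 (adjusted p = 0.968 with an estimated correlation) became 0.173 without 10 month replicate 1 and 0.0596 and 0.0572 without 3 month replicates 1 and 3. Endothelial genes had 7 lower and 1 higher of 21 (9 and 1 adjusted over the list alone; list adjusted p = 0.00217), with adjusted p = 0.977 with an estimated correlation and 0.0898 without 10 month replicate 2. The blood-brain barrier transporter gene Slco1a4 fell by 1.34 on the log2 scale (SE 0.27). Cholesterol synthesis genes had 8 lower and 2 higher of 25 (10 and 2 adjusted over the list alone; list adjusted p = 0.0254), with adjusted p = 0.977 with an estimated correlation. Hmgcs1, which makes HMG-CoA, was at -0.71 ± 0.14. The cholesterol call was lost without 10 month replicate 1 (0.0701) or 3 month replicates 1 (0.0697) or 3 (0.0572).

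Over 10 against 3 months 1862 genes rose and 1812 fell, 550 and 209 of them by at least 2-fold. The total of 3674 became 1052 without 10 month replicate 1 and 1942 without 10 month replicate 2. Vim was higher (0.69 ± 0.17), but not without 10 month replicate 1 (0.49). Myc (0.46 ± 0.26), Gfap (0.37 ± 0.22), Apoe (0.54 ± 0.25), Tardbp (0.28 ± 0.13), Mycn (-0.09 ± 0.30), Max (-0.01 ± 0.10), Serpina3n (-0.13 ± 0.19) and Cdkn1a (-0.16 ± 0.22) did not pass, with adjusted p of at least 0.128. MYC target genes had 7 higher and 1 lower of 68 (2 and 0 adjusted over the list alone) and were not called as a list (adjusted p = 0.819, mean 0.05, median 0.00).

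Between 6 and 10 months (n = 5 and 2) 93 genes rose and 54 fell. Jun (chromosome 4, 95049034 to 95052222) rose by 0.98 ± 0.13, from 138 to 272 CPM (adjusted p = 0.00754). The kinesin motor gene Kif5a rose by 1.5 ± 0.21, Bcas1, a gene of newly myelinating oligodendrocytes, by 1.49 ± 0.21 and the cytokine signalling inhibitor gene Socs3 by 1.15 ± 0.21, and Coq10b fell by 1.16 on the log2 scale (SE 0.18). In the same libraries CT010467.1 took 0.84% to 3.37% of counts at 6 months and 0.243% to 0.290% at 10 months, mt-Rnr2 a mean of 0.557% and 0.0955%, Lars2 a mean of 0.0839% and 0.017%, and the nuclear RNA Malat1 a mean of 0.218% and 0.0816%. All 23 named calls were lost in at least 1 alternative. Without 10 month replicate 2 the calls of Jun (0.90), Kif5a (0.95), Bcas1 (0.95), Socs3 (1.25) and Coq10b (-1.03) were lost, and that of Socs3 also without 10 month replicate 1 (1.05). Immediate early genes had 5 higher and 0 lower of 28 (13 and 0 adjusted over the list alone; list adjusted p = 1.32e-08), with adjusted p = 0.786 with an estimated correlation. Cholesterol synthesis genes had 1 lower and 0 higher of 25 (9 lower and 1 higher adjusted over the list alone; list adjusted p = 4.6e-06), with adjusted p = 0.928 with an estimated correlation. The called member was Msmo1 (-0.64 ± 0.15), lost without 6 month replicates 2 (-0.62), 3 (-0.60) and 4 (-0.69) and without 10 month replicates 1 (-0.61) and 2 (-0.66).

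Another 4 lists passed at 10 over 6 months, each losing its call without some library. Neuron genes had 0 of 22 past the test in edgeR (7 higher and 0 lower adjusted over the list alone), with a list adjusted p = 0.0029 and adjusted p = 0.928 with an estimated correlation. Their list value was 0.0968 without 10 month replicate 1. Oligodendrocyte precursor genes had 1 higher and 0 lower of 23 (5 and 0 adjusted over the list alone; list adjusted p = 0.0323), with adjusted p = 0.928 with an estimated correlation, 0.107 without 10 month replicate 1 and 0.111 without 6 month replicate 2. Ribosomal protein genes, in libraries where CT010467.1 took a mean of 2.38% and 0.266% of counts, had 0 of 57 past the test (0 adjusted over the list alone; median 0.12; list adjusted p = 0.0147), with adjusted p = 0.988 with an estimated correlation. That call was lost without 10 month replicate 2 (0.323) or 6 month replicates 2 (0.103) or 5 (0.0714). Endothelial genes had 0 of 21 past the test (0 adjusted over the list alone; median -0.38; list adjusted p = 0.0323), with adjusted p = 0.988 with an estimated correlation, 0.886 without 10 month replicate 2 and 0.45 without 6 month replicate 1. Of the 11 fixed genes none passed in edgeR, and the lowest adjusted p was 0.0931, for Cdkn1a (0.76 ± 0.22). Myc was at 0.55 ± 0.25 and Gfap at 0.38 ± 0.21. The total of 147 genes became 11 (10 higher and 1 lower) without 10 month replicate 2, 37 without 10 month replicate 1, and 320, 97, 59 and 70 without 6 month replicates 1, 2, 3 and 4. With RLE scaling 75 genes were higher and 70 lower, against 93 and 54, and with DESeq2 253 and 356.

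Between 3 and 6 months, O4 sorted oligodendrocytes (n = 4 and 4) gained vascular transcripts and lost transcripts of sterol synthesis and of precursor cells. Pecam1, an adhesion molecule of endothelium (chromosome 11, 106654217 to 106750628), rose by 2.73 ± 0.23, from 6.46 to 43.0 CPM (adjusted p = 0.000186). Endothelial genes had 21 higher of 21, as when adjusted over the list alone, with a median of 2.7, a list adjusted p = 1.2e-14 and adjusted p = 0.341 with an estimated correlation. Eng (2.80 ± 0.22) rose with them, as did Ly6c1 (2.90 ± 0.15) and Ly6a (2.83 ± 0.23), whose reads are uncertain because these genes resemble each other. Mural and fibroblast genes had 8 higher and 0 lower of 16 (9 and 0 adjusted over the list alone; list adjusted p = 0.000272), with adjusted p = 0.341 with an estimated correlation. The pericyte genes Pdgfrb (2.19 ± 0.22) and Rgs5 (2.32 ± 0.33, from 23.4 to 118 CPM) were among them. Among genes named by size of change, Edn1, which encodes endothelin 1, rose by 3.42 ± 0.36, Galnt15 by 3.82 ± 0.40, Xdh by 3.35 ± 0.31, Ushbp1 by 3.30 ± 0.51, the interleukin 1 receptor gene Il1r1 by 3.30 ± 0.34, Zfp366 by 3.21 ± 0.29, Notch4 by 3.20 ± 0.28, the angiotensin-converting enzyme gene Ace by 3.18 ± 0.57 and Emcn by 3.12 ± 0.48. The endothelial tight junction gene Cldn5 was at 8.03 ± 1.59 CPM at 3 months and 48.1 ± 21.2 CPM at 6 months.

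**Figure D3:**
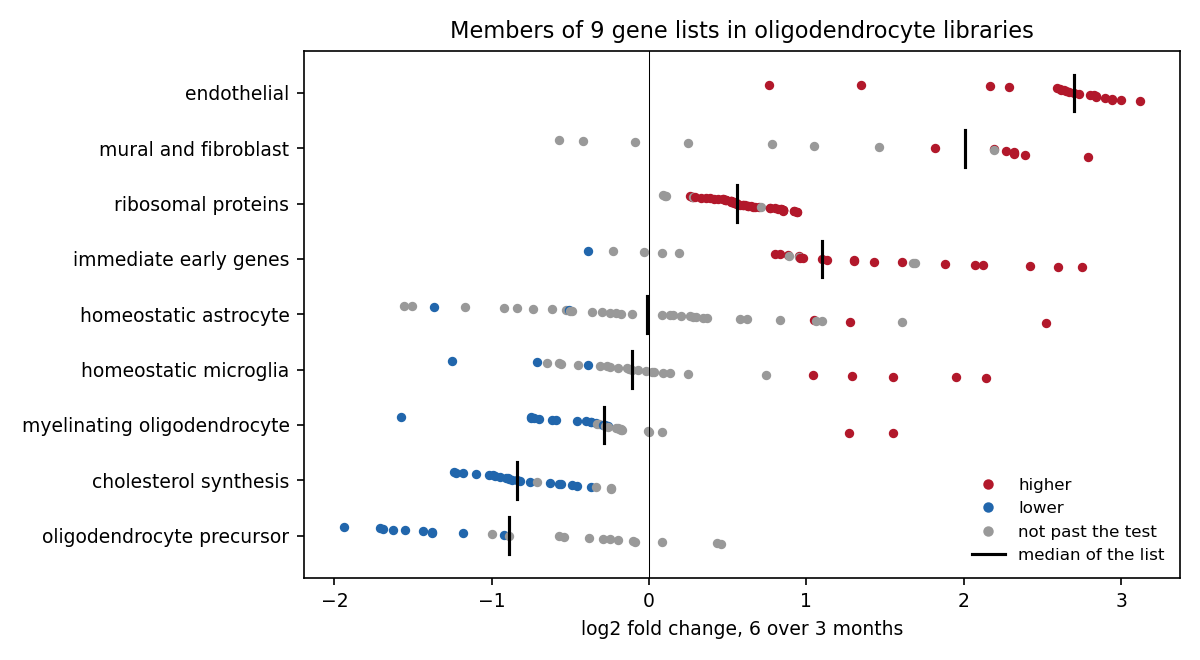
Log2 fold change of 6 over 3 months in oligodendrocyte libraries for the members of 9 gene lists, 1 point per gene, red for genes called higher, blue for genes called lower and grey for genes not past the test. Black bars are the medians of the lists, from 2.7 in endothelial to -0.89 in oligodendrocyte precursor genes.

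Cholesterol synthesis genes had 21 lower and 0 higher of 25 in 6 month oligodendrocytes (23 and 0 adjusted over the list alone), with a median of -0.84, a list adjusted p = 1.2e-14 and adjusted p = 0.341 with an estimated correlation. Fdft1, which encodes squalene synthase (chromosome 14, 63145150 to 63179578), fell by 0.98 on the log2 scale (SE 0.10), from 182 to 91.8 CPM, Mvk by 0.87 (SE 0.09) and Sc5d by 0.82 (SE 0.09). Oligodendrocyte precursor genes had 10 lower and 0 higher of 23 (11 and 0 adjusted over the list alone; median -0.89; list adjusted p = 3.84e-05), with adjusted p = 0.433 with an estimated correlation. The precursor growth factor receptor gene Pdgfra fell by 1.69 on the log2 scale (SE 0.31), Cspg5 by 1.71 (SE 0.30) and C1ql1 by 1.55 (SE 0.31). Cell cycle genes had 7 lower and 1 higher of 29, as when adjusted over the list alone, with a list adjusted p = 0.0158 and adjusted p = 0.341 with an estimated correlation. Mki67, a marker of dividing cells, fell by 2.32 (SE 0.44), while Cdk2 rose by 0.83 ± 0.16. Myelinating oligodendrocyte genes had 15 lower and 2 higher of 30, as when adjusted over the list alone, with a median of -0.29, a list adjusted p = 1.26e-06 and adjusted p = 0.258 with an estimated correlation. The lipid hydroxylase gene Fa2h (-0.59 ± 0.08) and the transferrin gene Trf (-0.75 ± 0.10, from 6500 to 3850 CPM) fell. Mbp of the same list did not fall, and was at 26700 ± 9810 CPM at 3 months and 75800 ± 26000 CPM at 6 months, where it took 4.83% to 9.51% of counts. Ribosomal protein genes had 52 higher and 0 lower of 57 (53 and 0 adjusted over the list alone), with a median of 0.56, a list adjusted p = 1.17e-14 and adjusted p = 0.433 with an estimated correlation. Rps21 rose by 0.92 ± 0.16 and Rpl26 by 0.85 ± 0.14. The mitochondrial share of counts was 4.06% to 4.44% at 3 months and 6.41% to 10.0% at 6 months. The mean share of CT010467.1 was 3.13% and 1.06%, and that of Lars2 0.174% and 0.0429%. The channel gene Cacna1b (-2.66 ± 0.22), Fibin (-1.94 ± 0.20), the adrenergic receptor gene Adra1b (-1.85 ± 0.18), Gjb2 (-1.85 ± 0.34) and Cd44 (-1.82 ± 0.31) also fell.

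Some reactive, immune and matrix lists rose in the same 6 month oligodendrocyte libraries, beside the endothelial genes and a share of CT010467.1 that was 3.13% at 3 months and 1.06% at 6 months. Immediate early genes had 18 higher and 1 lower of 27 (20 and 1 adjusted over the list alone; list adjusted p = 3.26e-08), with adjusted p = 0.341 with an estimated correlation. Klf2, a flow-responsive endothelial factor gene, rose by 2.6 ± 0.27, Fosl2 by 1.88 ± 0.22, Nr4a1 by 1.43 ± 0.16 and Junb by 0.96 ± 0.11. Interferon response genes had 16 higher and 0 lower of 31 (21 and 0 adjusted over the list alone; list adjusted p = 7.11e-06), with adjusted p = 0.494 with an estimated correlation, and Slfn5 rose by 3.17 ± 0.46. A1 astrocyte genes had 8 higher and 0 lower of 12 (10 and 0 adjusted over the list alone; list adjusted p = 0.000272), with adjusted p = 0.341 with an estimated correlation, and Gbp2 rose by 2.30 ± 0.39. Pan-reactive genes had 5 higher and 1 lower of 8 (6 and 1 adjusted over the list alone; list adjusted p = 0.00544), with adjusted p = 0.369 with an estimated correlation. Vim rose by 1.98 ± 0.25, the ceruloplasmin gene Cp by 1.88 ± 0.17 and Osmr, a cytokine receptor gene, by 3.04 ± 0.38, while Cd44 of the same list fell. A2 astrocyte genes had 4 higher and 0 lower of 6, as when adjusted over the list alone, with a list adjusted p = 0.014 and adjusted p = 0.341 with an estimated correlation. Extracellular matrix genes had 14 higher and 2 lower of 33 (15 and 2 adjusted over the list alone; list adjusted p = 0.00635), with adjusted p = 0.433 with an estimated correlation. Col4a1 (2.42 ± 0.23) and Col4a2 (2.41 ± 0.14), the collagens of basement membrane, rose and the protease gene Mmp2 fell by 1.10 on the log2 scale (SE 0.14).

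Neuron genes had 11 higher and 0 lower of 21 in the 6 month oligodendrocyte libraries (13 and 0 adjusted over the list alone; list adjusted p = 0.00101), with adjusted p = 0.433 with an estimated correlation, and the synaptic gene Snap25 rose by 1.42 ± 0.27, from 14.9 to 40.0 CPM. Ependymal and choroid plexus genes had 2 higher and 0 lower of 11 (8 and 0 adjusted over the list alone; list adjusted p = 0.0247), with adjusted p = 0.575 with an estimated correlation. That call was lost without 3 month replicate 3 (0.0501) or 6 month replicates 1 (0.0659), 2 (0.0524) or 3 (0.0739). Homeostatic astrocyte genes, at a median of -0.01, and homeostatic microglia genes, at -0.11, were not called. C3 rose by 1.25 ± 0.26 and Max, the partner of MYC, by 0.41 ± 0.09, from 51.4 to 68.3 CPM (adjusted p = 0.00781), and Mycn fell by 1.31 on the log2 scale (SE 0.29; adjusted p = 0.00945). Myc was at 0.01 ± 0.23 and did not pass, nor did Gfap (1 ± 0.38), Apoe, Serpina3n, Cdkn1a or C4b. Tardbp was called higher at 0.26 ± 0.08 with an adjusted p = 0.046, a call lost with RLE scaling (0.24), without a filter (0.20), with the filter at 1 CPM (0.21), without 3 month replicates 1 (0.23), 3 (0.25) or 4 (0.23) and without 6 month replicates 2 (0.22), 3 (0.21) or 4 (0.22). MYC target genes had 9 lower and 4 higher of 67 (5 and 4 adjusted over the list alone; list adjusted p = 0.065). In all 2096 genes rose and 1329 fell, 1114 and 199 of them by at least 2-fold. The total of 3425 became 2214 without 3 month replicate 1. Genes higher were 61.2% of those called, against 50.4% (1796 higher and 1771 lower) with the filter at 1 CPM and 50.5% (1852 and 1816) without the genes that took unequal shares of counts.

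Astrocytes and oligodendrocytes of 3 and 6 months (n = 9 and 8) were compared to show how the sorts differed. The glutamate transporter gene Slc1a2 (chromosome 2, 102658659 to 102790784) was higher in astrocytes by 6.30 ± 0.26, Gja1, a gap junction gene, by 7.87 ± 0.34, the water channel gene Aqp4 by 6.34 ± 0.32 and Aldoc by 3.4 ± 0.14. The myelin genes Mbp (-4.21 ± 0.18) and Mog (-1.65 ± 0.10) and the precursor gene Pdgfra (-2.38 ± 0.25) were lower in astrocytes, as were Cx3cr1 of microglia (-1.60 ± 0.21) and Snap25 of neurons (-0.76 ± 0.20). Cldn5 did not pass (-0.38 ± 0.28). These values average both ages, and Snap25 and Cldn5 went opposite ways at 3 and 6 months. Snap25 was at 24.2 CPM in astrocytes and 15.2 CPM in oligodendrocytes at 3 months, and at 13.6 and 39.2 CPM at 6 months. Cldn5 was at 24.9 and 8.03 CPM at 3 months, and at 14.9 and 48.1 CPM at 6 months. Homeostatic astrocyte genes had 36 higher and 1 lower of 38 (list adjusted p = 7.43e-14), with adjusted p = 0.53 with an estimated correlation, and astrocyte synapse genes 24 higher and 3 lower of 30 (2.8e-05), with adjusted p = 0.53 with an estimated correlation. Myelinating oligodendrocyte genes had 30 lower of 30 (1.16e-12), with adjusted p = 0.53 with an estimated correlation, and newly formed oligodendrocyte genes 17 lower and 2 higher of 20 (4.3e-06), with adjusted p = 0.53 with an estimated correlation. These 4 counts were the same adjusted over the list alone.

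Ribosomal protein genes had 54 lower and 0 higher of 57 in astrocytes (list adjusted p = 7.43e-14), with adjusted p = 0.649 with an estimated correlation, and immediate early genes 19 lower and 4 higher of 28 (0.00783), with adjusted p = 0.652 with an estimated correlation. Glycolysis genes had 16 higher and 1 lower of 20 (16 and 2 adjusted over the list alone; list adjusted p = 0.00894), with adjusted p = 0.711 with an estimated correlation. Ependymal and choroid plexus genes had 11 higher and 4 lower of 18 (0.0181), with adjusted p = 0.711 with an estimated correlation. Disease-associated oligodendrocyte genes had 14 lower and 3 higher of 20 (15 and 3 adjusted over the list alone; list adjusted p = 0.031), with adjusted p = 0.652 with an estimated correlation. Red blood cell genes had 8 lower of 8 (0.031), with adjusted p = 0.649 with an estimated correlation. For ribosomal, immediate early, ependymal and red blood cell genes the counts were the same adjusted over the list alone. In total 6328 genes were higher and 5874 lower in astrocytes, of 16363 tested.

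The change from 3 to 6 months was tested for a difference between astrocytes and oligodendrocytes in the same fit. Gjb2, a gap junction gene, differed by 2.42 ± 0.33, with 0.49 in astrocytes and -1.85 in oligodendrocytes, and Smim5 by 2.37 ± 0.35, with 0.69 and -1.59. Both effects of each gene passed in their own cell type. Tmem72 differed by -4.81 ± 1.02, with -1.96 and 2.95, and Mfrp by -4.76 ± 1.06, with -1.95 and 2.91, and their effects also passed in each cell type. Prlr (-5.26 ± 1.06), Kl (-5.14 ± 1.19) and Atp2b3 (-4.92 ± 1.11) differed too, but their own changes in oligodendrocytes did not pass. The choroid plexus gene Ttr was at 721 ± 487 and 162 ± 64.8 CPM in 3 and 6 month astrocytes and at 441 ± 424 and 2260 ± 1640 CPM in oligodendrocytes, with 33.7 to 888 CPM between the 3 month and 267 to 3620 CPM between the 6 month oligodendrocyte libraries. Endothelial genes had a lower age effect in astrocytes in 20 and a higher one in 0 of 21 (21 and 0 adjusted over the list alone; list adjusted p = 6.95e-20), with adjusted p = 0.206 with an estimated correlation. Cholesterol synthesis genes had a higher age effect in astrocytes in 20 and a lower one in 0 of 25 (23 and 0 adjusted over the list alone; list adjusted p = 1.52e-15), with adjusted p = 0.206 with an estimated correlation. Ribosomal protein genes had a lower age effect in astrocytes in 29 and a higher one in 0 of 57 (44 and 0 adjusted over the list alone; list adjusted p = 3.37e-13), with adjusted p = 0.476 with an estimated correlation. The age effect was higher in astrocytes for 1053 genes and lower for 1631.

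Microglia from cortices were compared between 10 and 3 months (n = 4 and 3) for changes over that interval. Spp1, which encodes the secreted phosphoprotein osteopontin (ENSMUSG00000029304; chromosome 5, 104435118 to 104441050), rose by 3.90 ± 0.22, from 10.6 to 157 CPM (adjusted p = 5.74e-08). Gpnmb (ENSMUSG00000029816), a lysosomal membrane glycoprotein gene, rose by 3.46 ± 0.26, from 7.37 to 81.4 CPM, the lipid carrier gene Apoe (ENSMUSG00000002985) by 1.94 ± 0.19, from 893 to 3430 CPM, and the phagocytic receptor gene Axl (ENSMUSG00000002602) by 2.31 ± 0.30. The chemokine gene Cxcl14 was called higher (4.46 ± 0.75), except in limma-voom (4.68). The early response gene Nr4a1 fell by 2.53 on the log2 scale (SE 0.35), from 165 to 28.5 CPM, and Jund by 0.74 (SE 0.13). The heat shock genes Hspa1b (-1.86 ± 0.28) and Hspa1a (-1.43 ± 0.22) fell as well, and their assignment is uncertain because they are nearly identical.

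**Figure D4:**
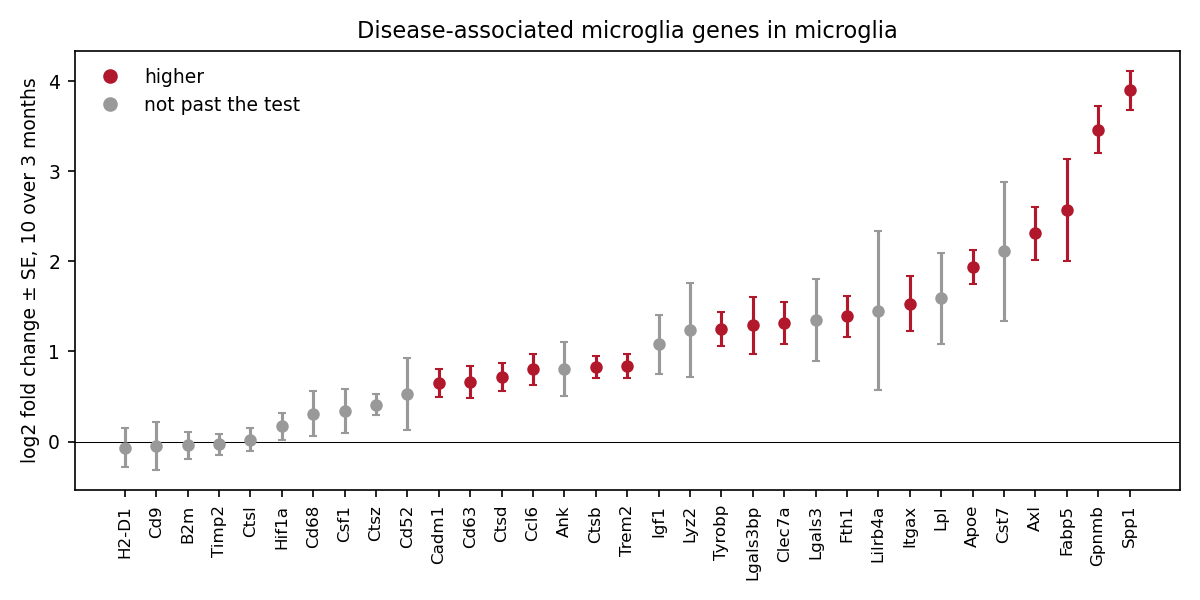
Log2 fold change of 10 over 3 months in microglia for 33 disease-associated microglia genes, points with bars of ± 1 SE, 4 against 3 libraries. Red points are the 16 genes called higher, up to Spp1 at 3.90, and grey points did not pass.

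Disease-associated microglia genes, a state described in neurodegeneration, had 16 higher and 0 lower of 33 (22 and 0 adjusted over the list alone), with a median of 0.84, a list adjusted p = 2.5e-12 and adjusted p = 0.459 with an estimated correlation. Ribosomal protein genes had 14 higher and 0 lower of 56 (28 and 0 adjusted over the list alone; list adjusted p = 1.6e-07), with adjusted p = 0.522 with an estimated correlation, and Rpl6 (0.96 ± 0.15) and Rps20 (0.91 ± 0.15) rose. Oxidative phosphorylation genes had 3 higher and 0 lower of 52 (7 and 0 adjusted over the list alone; list adjusted p = 4.42e-05), with adjusted p = 0.522 with an estimated correlation. Ndufb9 of this list (1.58 ± 0.30) lost its call without 10 month replicate 1 (1.41). Homeostatic astrocyte genes had 2 higher and 0 lower of 26 (3 and 0 adjusted over the list alone; list adjusted p = 0.00292), with adjusted p = 0.343 with an estimated correlation. Slc1a2 of this list was at 16.6 and 35.0 CPM (1.07 ± 0.25). Its call was lost without 10 month replicates 1 (1.02), 2 (1.07) and 3 (0.97) and 3 month replicates 2 (1) and 3 (1.04). Myelinating oligodendrocyte genes had 3 higher and 0 lower of 30 (8 and 0 adjusted over the list alone; list adjusted p = 0.00297), with adjusted p = 0.62 with an estimated correlation and 0.0987 without 3 month replicate 1. Trf of this list, which is also a gene of iron transport, rose by 0.77 ± 0.12, from 670 to 1140 CPM.

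Immediate early genes had 7 lower and 1 higher of 28 in 10 month microglia (8 and 3 adjusted over the list alone; list adjusted p = 0.0133), with adjusted p = 0.522 with an estimated correlation. That list value was 0.145 without 10 month replicate 2 and 0.0596 without 3 month replicate 1. MYC network genes had 1 lower and 0 higher of 11 (2 and 0 adjusted over the list alone; median -0.48; list adjusted p = 0.00693), with adjusted p = 0.459 with an estimated correlation. The member that passed, the glucose-responsive factor gene Mlxipl (-0.57 ± 0.12), lost its call without 10 month replicates 1 (-0.55), 3 (-0.57) and 4 (-0.51) and 3 month replicate 3 (-0.53). MYC target genes had 1 lower and 0 higher of 66, as when adjusted over the list alone (list adjusted p = 0.951). Of the 11 fixed genes 8 were tested and Apoe alone passed; Myc was at 0.10 ± 0.65, Max at -0.48 ± 0.23, C3 at 0.44 ± 0.61, C4b at 1.08 ± 0.51, Vim at 0.78 ± 0.30, Cdkn1a at 0.72 ± 0.26 and Tardbp at 0.00 ± 0.17. In all 239 genes rose and 156 fell, 120 and 39 of them by at least 2-fold. The total of 395 became 51 (40 higher and 11 lower) without 10 month replicate 1, 91 without 10 month replicate 3, 116 without 10 month replicate 4 and 193 without 3 month replicate 3. It was larger with DESeq2 and with every gene kept, as given below. Of 36 named calls 12 were kept with each library left out in turn. A single gene, ENSMUSG00000119584, took 17.9% to 27.0% of counts in these libraries.

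Omomyc was compared with vehicle in cultured astrocytes (n = 3 and 3) to show which transcripts change with this treatment. In the planned fit 0 genes rose and 3 fell in edgeR, against 18 and 79 in DESeq2 and 0 and 2 in limma-voom, with 1022 genes at an unadjusted p under 0.05 where chance gives 806. The 3 genes were Vgf, a secreted neuropeptide precursor gene (-1.48 ± 0.12), the inositol phosphatase gene Inpp5j (-1.39 ± 0.12) and Gm45837, a predicted gene named here after its value was seen (each adjusted p = 0.0497). The call of Inpp5j was lost in each fit with 1 library left out, and that of Vgf was lost in 5 of 6, without each vehicle library (-1.53, -1.42 and -1.5) and without Omomyc replicates 1 (-1.40) and 2 (-1.44). Without a library the total was 0, or 1 without Omomyc replicate 3. With a term for the inferred replicate pair, 360 genes rose and 296 fell, 44 and 48 of them by at least 2-fold. The total of 656 became 1085 without replicate 2 and 1130 without replicate 3. The genes below are given from the fit with pairs, and apart from Vgf and Inpp5j none was called without the pair term.

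In the fit without pairs 14 lists passed in camera, with 0 members past the test in edgeR. NF-kB cytokine and chemokine genes were lower (7 of 27 adjusted over the list alone; median -0.38; list adjusted p = 8.39e-09), with adjusted p = 0.44 with an estimated correlation. Pan-reactive astrocyte genes (3 of 13 lower adjusted over the list alone; 1.16e-05), A2 astrocyte genes (3 of 11; 0.0118) and immediate early genes (5 of 30; 0.000266) were lower too, with adjusted p = 0.44, 0.44 and 0.549 with an estimated correlation. The other 10 had 0 genes past the test adjusted over the list alone. Cell cycle genes were higher (median 0.28; 4.1e-13), with adjusted p = 0.556 with an estimated correlation. Cholesterol synthesis (0.000313) and homeostatic microglia genes (0.00193) were higher and oxidative phosphorylation (9.16e-06), integrated stress response (0.000661), glycolysis (0.0037) and ribosomal protein genes (0.0267) lower, with adjusted p = 0.585, 0.556, 0.723, 0.556, 0.556 and 0.844 with an estimated correlation. Myelinating oligodendrocyte genes (0.0443) and newly formed oligodendrocyte genes (0.034) were higher and neuron genes (0.034) lower, with adjusted p = 0.455, 0.44 and 0.44 with an estimated correlation, and these 3 did not pass with the pair term (0.0636, 0.0571 and 0.054).

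Single libraries ended several of these list calls in the fit without pairs. Without vehicle replicate 1 cholesterol synthesis (0.0998), homeostatic microglia (0.0998), myelinating oligodendrocyte (0.0901) and newly formed oligodendrocyte genes (0.0651) did not pass. Without vehicle replicate 2 oxidative phosphorylation (0.96), glycolysis (0.136), ribosomal protein (0.0575), neuron (0.0907) and newly formed oligodendrocyte genes (0.0698) did not, and without vehicle replicate 3 integrated stress response (0.097), ribosomal protein (0.107) and newly formed oligodendrocyte genes (0.0707). Without Omomyc replicate 1 ribosomal protein (0.807) and neuron genes (0.0877) did not pass, and without Omomyc replicate 2 myelinating (0.0652) and newly formed oligodendrocyte genes (0.0887). Without Omomyc replicate 3 glycolysis (0.0582), homeostatic microglia (0.0877), myelinating oligodendrocyte (0.191), neuron (0.0605) and newly formed oligodendrocyte genes (0.067) did not.

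**Figure D5:**
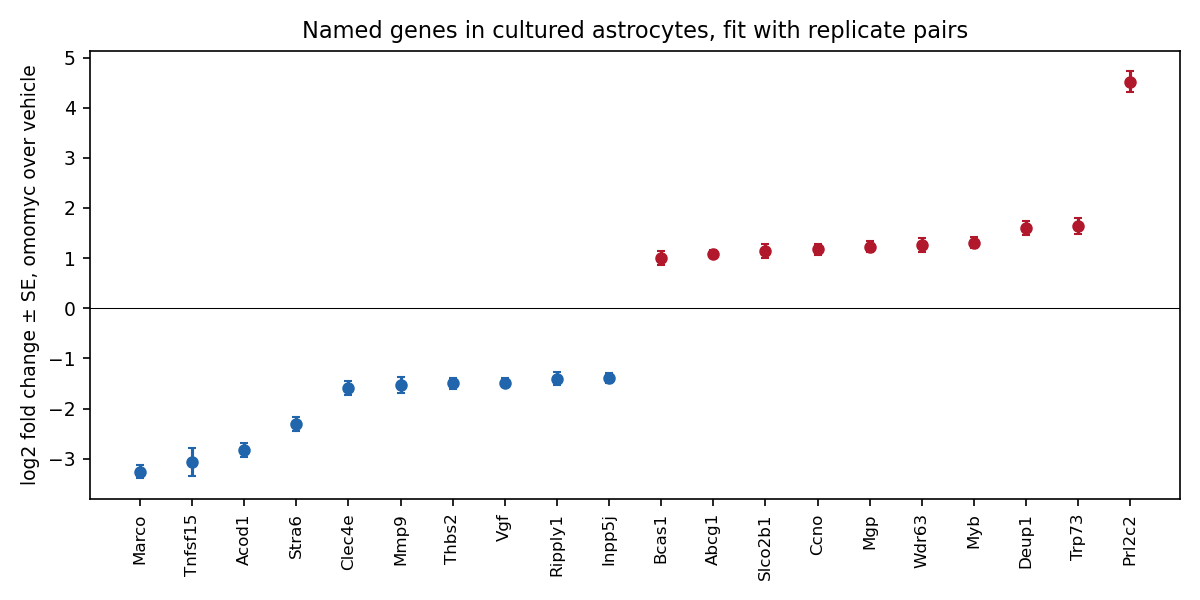
Log2 fold change of Omomyc over vehicle for the 20 named genes in cultured astrocytes from the fit with replicate pairs, points with bars of ± 1 SE, 3 pairs. Blue genes were lower, down to Marco at -3.26, and red genes higher, up to Prl2c2 at 4.52, which was at 0.329 CPM with vehicle.

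The scavenger receptor gene Marco (ENSMUSG00000026390.7; chromosome 1, 120474538 to 120505024) fell by 3.26 on the log2 scale with Omomyc (SE 0.13; adjusted p = 5.5e-05), from 34.7 to 3.66 CPM. The microglial gene Cx3cr1 was at 188, 197 and 343 CPM in vehicle replicates 1 to 3 and at 219, 251 and 442 CPM in Omomyc replicates 1 to 3. The cultures thus held microglial RNA, and which cells the changes in this fit came from was not tested. Tnfsf15 (-3.06 ± 0.28), the itaconate synthesis gene Acod1 (-2.82 ± 0.14), the retinol transport gene Stra6 (-2.30 ± 0.14), the pattern recognition receptor gene Clec4e (-1.59 ± 0.13), the protease gene Mmp9 (-1.53 ± 0.15) and the matrix gene Thbs2 (-1.5 ± 0.11, from 187 to 61.6 CPM) also fell. Trp73 (1.65 ± 0.16), Deup1 (1.60 ± 0.14), Myb (1.31 ± 0.11), Ccno (1.18 ± 0.11), the matrix protein gene Mgp (1.23 ± 0.11) and the lipid exporter gene Abcg1 (1.08 ± 0.08) rose. Prl2c2 rose by 4.52 ± 0.21, from 0.329 ± 0.487 to 7.45 ± 9.79 CPM. Its fold rests on few counts with vehicle, its level varied widely between libraries, and its reads are uncertain because close relatives exist. NF-kB cytokine and chemokine genes had 10 lower and 1 higher of 27 (19 and 2 adjusted over the list alone; list adjusted p = 1.44e-07), with adjusted p = 0.696 with an estimated correlation. The chemokine gene Ccl2 fell by 1.22 on the log2 scale (SE 0.10), Nfkbiz by 0.64 (SE 0.07) and the inhibitor gene Nfkbia by 0.55 (SE 0.08), while the prostaglandin synthesis gene Ptgs2 rose by 0.71 ± 0.07. Pan-reactive astrocyte genes had 4 lower and 0 higher of 13 (9 and 0 adjusted over the list alone; list adjusted p = 5.51e-05), with adjusted p = 0.711 with an estimated correlation, and Lcn2 (-1.18 ± 0.13) and Steap4 (-0.87 ± 0.10) fell. A2 astrocyte genes had 4 lower and 1 higher of 11 (6 and 1 adjusted over the list alone; list adjusted p = 0.0265), with adjusted p = 0.696 with an estimated correlation, and Ptx3 fell by 0.80 (SE 0.07).

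Immediate early genes had 7 lower and 0 higher of 30 with Omomyc in the fit with pairs (9 and 1 adjusted over the list alone; list adjusted p = 8.48e-05), with adjusted p = 0.696 with an estimated correlation, and Junb fell by 0.47 on the log2 scale (SE 0.07). Integrated stress response genes had 3 lower and 0 higher of 30 (5 and 0 adjusted over the list alone; list adjusted p = 9.65e-06), with adjusted p = 0.696 with an estimated correlation, and the cystine transporter gene Slc7a11 fell by 0.82 (SE 0.09). Cell cycle genes had 3 higher and 0 lower of 43 (21 and 0 adjusted over the list alone; list adjusted p = 1.44e-07), with adjusted p = 0.764 with an estimated correlation. Cenpf of this list (0.74 ± 0.14) lost its call without replicate 2 (0.56). Homeostatic microglia genes had 12 higher and 0 lower of 27 (16 and 1 adjusted over the list alone; list adjusted p = 4.96e-06), with adjusted p = 0.696 with an estimated correlation, and P2ry12 (0.84 ± 0.09) and Tmem119 (0.62 ± 0.06) rose. Cx3cr1 was higher in the Omomyc library of each pair, with means of 243 CPM for vehicle and 304 CPM for Omomyc. Cholesterol synthesis genes had 2 higher and 0 lower of 25 (8 and 0 adjusted over the list alone; list adjusted p = 0.000654), with adjusted p = 0.696 with an estimated correlation. Oxidative phosphorylation, glycolysis and ribosomal protein genes had 0 members past the test in edgeR and list adjusted p of 7.62e-06, 0.00302 and 0.013, with adjusted p = 0.764, 0.764 and 0.776 with an estimated correlation.

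MYC target genes had 2 higher and 0 lower of 69 with Omomyc in the fit with pairs, with a median of -0.05, and were not called (list adjusted p = 0.492). Myc was at 32.3 CPM with vehicle and 33.9 CPM with Omomyc (0.07 ± 0.07) and did not pass. Mycn was called lower (-0.79 ± 0.17, adjusted p = 0.0439), and the call was lost without each pair (-0.89, -0.77 and -0.72) and in DESeq2 (-0.79). Gfap (-0.21 ± 0.08), C3 (-0.30 ± 0.09), Vim (0.02 ± 0.08), Tardbp (0.03 ± 0.06) and Max (-0.04 ± 0.06) did not pass. The 200 genes with the smallest p each way in the fit with pairs were then tested as sets in the 5 age comparisons of sorted cells, which share no library with the cultures. In camera 0 of 10 tests passed, with the lowest adjusted p = 0.0792 for genes higher with Omomyc in oligodendrocytes at 6 over 3 months (48 higher and 11 lower of 143 measured), and 0 of 10 passed with an estimated correlation (lowest adjusted p = 0.496).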

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

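The tests of explanations for patterns in this part were chosen after seeing results. The difference of age effects, its list tests and the counts over relabelled samples were chosen before the data were examined. Between 3 and 6 months, the difference between the age effects of astrocytes and oligodendrocytes was tested within 1 fit, and 2684 genes differed. Endothelial (20 lower and 0 higher of 21; 6.95e-20), mural and fibroblast (13 lower and 0 higher of 20; 8.02e-08), ribosomal protein (29 lower and 0 higher of 57; 3.37e-13), immediate early (11 lower and 0 higher of 28; 4.87e-08), extracellular matrix (18 lower and 0 higher of 37; 2.13e-05), interferon response (9 lower and 0 higher of 33; 0.000122), neuron (12 lower and 0 higher of 24; 0.000192) and newly formed oligodendrocyte genes (4 lower and 0 higher of 20; 0.00184) had a lower age effect in astrocytes. Pan-reactive (5 lower and 1 higher of 11; 0.01) and A1 astrocyte genes (5 lower and 1 higher of 12; 0.0146) did so as well. Cholesterol synthesis (20 higher and 0 lower of 25; 1.52e-15) and oligodendrocyte precursor genes (10 higher and 0 lower of 23; 0.00059) had a higher age effect in astrocytes. With an estimated correlation, none of these lists passed, and the adjusted p were 0.206 for endothelial, mural and cholesterol genes and between 0.262 and 0.591 for the others.

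MYC target genes had a higher age effect in astrocytes, with 5 higher and 3 lower of 68, a median difference of 0.15, a list adjusted p = 0.025 and adjusted p = 0.587 with an estimated correlation. The call was lost without astrocyte 6 month replicates 1 (0.0834) or 3 (0.0525) and without oligodendrocyte 6 month replicates 3 (0.0501) or 4 (0.0686). A2 astrocyte genes had 4 lower and 0 higher of 8 (0.0429), with adjusted p = 0.447 with an estimated correlation, and were not called without astrocyte 3 month replicates 2 (0.0544) or 3 (0.0653), astrocyte 6 month replicates 1 (0.0924), 2 (0.0942), 3 (0.0525) or 4 (0.0648), or oligodendrocyte 3 month replicate 2 (0.0603) or 6 month replicate 4 (0.0806). Ependymal and choroid plexus genes had 7 lower and 0 higher of 18 (0.0251), with adjusted p = 0.719 with an estimated correlation. They were not called without astrocyte 3 month replicate 3 (0.0806), astrocyte 6 month replicates 1 (0.0652), 2 (0.0599) or 3 (0.0527), or oligodendrocyte 3 month replicate 3 (0.0793) or 6 month replicates 2 (0.0588) or 3 (0.0568). Genes with the largest differences were named among those with a mean of at least 5 CPM over a pool of both cell types. The pool was 6 month astrocyte and 3 month oligodendrocyte libraries for the higher side. For the lower side it was 3 month astrocyte and 6 month oligodendrocyte libraries. The genes were Wdr93 (3.08), Ranbp3l (2.66), Gjb2 (2.42), Smim5 (2.37) and Dbpht2 (2.26) on the higher side. On the lower side they were Prlr (-5.26), Kl (-5.14), Atp2b3 (-4.92), Tmem72 (-4.81) and Mfrp (-4.76). Wdr93 and Ranbp3l were too low to be tested in oligodendrocytes alone, and in astrocytes Ranbp3l did not pass (-0.03, adjusted p = 0.901). The call of Ranbp3l was lost without astrocyte 3 month replicates 3 (2.63) or 4 (2.55), astrocyte 6 month replicates 3 (2.64) or 4 (2.59), oligodendrocyte 3 month replicates 1 (2.56), 2 (2.51) or 3 (2.7), or oligodendrocyte 6 month replicates 1 (2.39), 2 (2.26) or 4 (2.47).

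In 24 of 414 groups of 4 or 5 libraries, the highest or lowest library lay far from the others by Dixon's ratio, where chance gives about 1 in 20, or 20.7. In 3 month astrocytes the ratios were 0.879 for Hif3a and 0.858 for Tmem59l (replicate 4), 0.993 for Pcdhb11 and 0.891 for Cdh5 (replicate 1) and 0.892 for C1qb (replicate 2). In 6 month astrocytes they were 0.711 for Baiap3, 0.83 for Ier2, 0.714 for Lrrc8c, 0.79 for Jun and 0.733 for Egr3 (replicate 2), 0.799 for T2, 0.829 for H2-T23 and 0.75 for Kif5a (replicate 1), and 0.734 for Serpina3n and 0.835 for Rpl10a (replicate 5). In 3 month oligodendrocytes they were 0.841 for Lars2 and 0.961 for Rpl38 (replicate 4), 0.913 for Cp (replicate 3) and 0.893 for Junb (replicate 1). In 6 month oligodendrocytes replicate 1 had ratios of 0.904 for Tardbp and 0.978 for Cdkn1a, which was at 212 CPM against a median of 23.4 CPM in the other libraries. In 10 month microglia they were 0.907 for total counts (replicate 1), 0.851 for Hist2h2ac (replicate 3) and 0.853 for S100b (replicate 4).

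With samples relabelled at random, 1 of 100 splits, the real one, called as many genes in astrocytes at 6 over 3 months (2359, highest other 833). Chance is therefore unlikely there, but with this number of splits it is not excluded. The same held in oligodendrocytes (1 of 35 splits; 3425, highest other 0), microglia (1 of 35; 395, highest other 62), between the cell types (1 of 100; 12202, highest other 904) and for the difference of age effects (1 of 100; 2684, highest other 2148). For the difference of age effects, other splits called up to 2148 genes. Ages were shuffled there within each cell type, and a split could keep or mirror the real ages of 1 cell type. The highest count therefore cannot show how many calls arise without the real labels. Relabelling cannot part age from a batch that the libraries of an age share. For Omomyc the splits were too few, with 3 genes in the real split of 10 and 0 in the highest other, and 656 and 0 among 4 splits with pairs.

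In 3 and 6 month astrocytes, clock genes moved in opposite directions. Of 11 genes driven by CLOCK and BMAL1 9 were higher at 6 months (median 0.71), and of 5 genes of the opposite phase 3 were lower (median -0.61), among them Arntl, which encodes BMAL1 (-0.95 ± 0.10). Their medians differed by 1.32, with a lowest value of 1.23 without 3 month replicate 4, so a single library was not the cause. A different time of day at collection and an effect of age cannot be told apart, because this difference is the pattern itself and collection times are not given in the sources used here.

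In 6 month oligodendrocyte libraries, vascular cells in the sorts may account for the higher endothelial genes. Of 9 endothelial genes outside the list 88.9% rose by more than 1 on the log2 scale, such as Adgrf5 (2.94 ± 0.24), Erg (2.91 ± 0.33) and Sox17 (2.76 ± 0.36), while Mfsd2a did not pass (0.81 ± 0.35). These genes repeat the pattern in the same libraries. They therefore cannot tell vascular cells in the sorts from another cause of higher endothelial genes. A lower share of oligodendrocyte RNA alone would have raised astrocyte and microglia genes too, but the endothelial median lay 2.71 above the higher of their medians. The lowest endothelial median with a library left out was 2.37. No biological explanation was tested.

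In 10 month microglia, RNA of astrocytes and oligodendrocytes in the sorts could have raised disease-associated microglia genes. The 13 members that were low in astrocyte and oligodendrocyte libraries had a median of 1.08, with 6 called higher. This argues against such RNA as the cause for those 13. The other 20 had a median of 0.82, with 10 called higher. For these the test cannot decide, because they were not low in the other cells. Apoe, for example, was at 885 CPM in 3 month microglia and 6110 CPM in astrocytes. The lowest median of the list with a library left out was 0.83, without replicate 1 of 10 months. The age group remains as an explanation that was not tested against mice without the transgene.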

How the results depend on the processing

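The following counts cover only genes named by the rule, which favours large changes and small p, and do not stand for all called genes. Of 305 called results of these genes, alternatives gave 4395 values. Of these values 3990 kept direction and call, 405 lost the call and 0 reversed. Of 181 results not called for named genes, 2253 values gave 135 calls and 55 changes of sign. With every gene kept, 578 genes changed in astrocytes at 10 over 6 months and 730 in microglia, and with DESeq2 609 and 748, against 147 and 395. The culture fit without pairs called 3 genes, and 0 with the filter at 1 CPM, 97 with DESeq2 and 656 with the replicate block. In the age comparisons libraries shared only a number (mean correlation of same-numbered libraries -0.14 to 0.05), and a replicate block gave 56 genes at 10 over 6 months and 211 in microglia. It gave 9 lists against 5 at 10 over 3 months, adding ribosomal protein, antigen presentation and complement genes (higher) and mural genes (lower), each at 0.0457. At 10 over 6 months it added cell cycle genes (higher; 0.00205), homeostatic astrocyte (lower; 0.00205) and mural genes (lower; 0.0292), and in microglia oligodendrocyte precursor genes (higher; 0.0435). It ended the list calls of endothelial genes at 6 over 3 months (0.127) and neuron genes at 10 over 6 months (0.0601). Among gene calls stated above it ended those of Vim (0.34) and C1qc (1.03) at 6 over 3 months, Ttr (-5.22) at 10 over 3 months, Tardbp (0.25) in oligodendrocytes and Ranbp3l (2.56) for the difference, and no other stated call. With an estimated correlation 0 lists passed in each of the 8 comparisons. The sign of genes that had not passed changed for Myc (0.02 in limma-voom) in astrocytes at 6 over 3 months, Mycn (0.26) and Cdkn1a (0.01) at 10 over 3 months and Serpina3n (0.04) at 10 over 6 months with a replicate block. In oligodendrocytes it changed for Serpina3n (0.03) in limma-voom, Myc (-0.05 with every gene, -0.04 at 1 CPM, -0.03 in limma-voom, -0.02 with a replicate block, -0.05 without genes of unequal share) and Cdkn1a (-0.27 in limma-voom, -0.31 with a replicate block), and in microglia for Myc (-0.27 in limma-voom). With 1 library left out, genes that had not passed changed sign in some fits: Gfap (-0.10 to 0.11), Serpina3n (-0.11 to 0.10) and Myc (-0.23 to 0.07) in astrocytes at 6 over 3 months, Gfap (-0.01 to 0.67), Mycn (-0.19 to 0.05), Max (-0.06 to 0.04), Serpina3n (-0.48 to 0.16) and Cdkn1a (-0.28 to 0.10) at 10 over 3 months, Serpina3n (-0.46 to 0.18) and C3 (-0.07 to 0.91) at 10 over 6 months. The same held for Serpina3n (-0.61 to 0.22), Myc (-0.12 to 0.20), Cdkn1a (-1.09 to 0.80) and C4b (-0.04 to 0.51) in oligodendrocytes, Myc (-0.39 to 0.57) and C3 (-0.01 to 2.15) in microglia. In culture it held for Apoe (-0.25 to 0.38), Cdkn1a (-0.11 to 0.06), Vim (-0.08 to 0.09) and Tardbp (-0.04 to 0.09) without pairs and for Apoe (-0.08 to 0.24), Cdkn1a (-0.04 to 0.03), Vim (-0.02 to 0.08), Tardbp (-0.04 to 0.08), C4b (-0.10 to 0.09) and Aldoa (-0.01 to 0.69) with pairs. Leaving out 1 library gave 1161 to 2637 genes in astrocytes at 6 over 3 months, 1052 to 3713 at 10 over 3, 11 to 320 at 10 over 6, 2214 to 4925 in oligodendrocytes, 51 to 396 in microglia, 11919 to 12438 between cell types, 2089 to 3508 for the difference of age effects, 0 to 1 in culture and 566 to 1130 with pairs. Lists called were 5 to 10, 3 to 7, 4 to 9, 14 to 18, 7 to 9, 10 to 10, 12 to 17 and 9 to 14 in culture. The cause was not tested for any of these. Microglia had 4145129 to 5612071 counts per library, a common biological coefficient of variation of 33.8% against 13% to 16.8% elsewhere, and 32.8% of simulated 2-fold changes recovered, and the share of depth in this was not tested.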

Other observations

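Clock genes were chosen for a closer look after seeing results. Dbp was at 51.9 ± 11 CPM at 3 months (n = 4), 161 ± 22.5 CPM at 6 months (n = 5) and 105 ± 8.77 CPM at 10 months (n = 2) in astrocytes, and Arntl at 43.8 ± 5.73, 22.9 ± 2.88 and 40.6 ± 1.84 CPM. At 10 over 3 months 4 of 11 genes driven by CLOCK and BMAL1 were higher (median 0.28) and 1 of 5 of the opposite phase was lower (median -0.12). At 10 over 6 months 2 of 11 were lower (median -0.54) and 2 of 5 higher (median 0.12). In oligodendrocytes at 6 over 3 months 1 of 11 was higher (median 0.15) and 3 of 5 higher (median 0.37), so the opposite movement of the groups was not seen there.

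The choroid plexus gene Ttr varied widely within groups. It was at 721 ± 487 CPM in 3 month, 162 ± 64.8 CPM in 6 month and 14.5 ± 20.4 CPM in 10 month astrocytes, at 441 ± 424 and 2260 ± 1640 CPM in 3 and 6 month oligodendrocytes, and at 1300 ± 1070 and 1190 ± 1240 CPM in 3 and 10 month microglia. The myelin gene Mbp was at 26700 ± 9810 CPM in 3 month and 75800 ± 26000 CPM in 6 month oligodendrocytes. Slc1a2 was at 16600 ± 2890 CPM in 3 month astrocytes and 174 ± 86.3 CPM in 3 month oligodendrocytes.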
